A study of Mus musculus with 92 samples.

How the data were processed

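The deposited tables held, for each of 92 arrays and 24613 probes, a signal intensity and a detection p-value. Per the file headers the intensity values were non-normalized, and what the authors' scanner software did to make them is not given in the sources used here; the values showed no background correction. The detection p-value of each probe was deposited with the signal, and how the authors computed it is not given in the sources used here. The series matrix deposited by the authors held log2 values whose normalization is not given in the sources used here. On all 92 arrays they kept the order of the signal, 90 arrays shared one distribution (median 7.42), and 2 dim spinal cord arrays shared another (median 6.38). Per the labels, tissue RNA was purified with RNeasy columns, blood RNA was collected in PAXgene tubes and depleted of globin transcripts, and biotinylated cRNA was made with the Ambion MessageAmp kit.

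Background was corrected and arrays were quantile normalized within each tissue with neqc of limma (offset 16), which inferred the mean and variance of the negative controls from the detection p-values. Of the probes 20984 had 1 gene symbol, 1 had several and 3628 had none, giving 15967 genes. Symbols were matched by Entrez identifier to the RefSeq genes of assembly GRCm38.p6 (20968 probes, 0 symbols changed); the build the authors used is not given in the sources used here. Lines without a probe identifier (7, with 0.00539% of the signal) were left out. A probe entered the tests of a tissue when its detection p-value was under 0.05 on at least 7 arrays of that tissue, and the brightest probe stood for its gene. Probes without a single gene symbol stayed in on their own and are counted as genes below.

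Arrays were grouped by tissue, genotype and age as the labels give them, with 7 or 8 arrays in each of 12 groups. The 308 pairs of arrays within groups held 0 identical pairs, with Spearman rho from 0.58 to 0.963 (median 0.912). The labels give no sex, and Uty, Kdm5d and Eif2s3y, of the Y chromosome, were detected on 0 of 92 arrays. Whether a replicate number stands for the same mouse in all 3 tissues is not given in the sources used here, so arrays were not paired.

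Genotypes were compared at 70 and at 100 days in each tissue, with the change of the genotype effect between the ages (the interaction) and the ages of the wild type. Limma fitted the 4 groups of a tissue together with moderated statistics, and p-values were adjusted by Benjamini and Hochberg at 0.05. Every p-value of a single gene in the text is from this limma fit, or from a limma fit under the alternative setting named beside it. Gene lists (37, of which those with at least 5 measured members were tested) were examined with camera of limma at a preset correlation of 0.01, with a correlation estimated from the data given beside it, and adjusted over the lists of a tissue and comparison. A list mean of an array is the mean, over its members, of the log2 value minus that of all wild type arrays of the tissue. Shared genes were counted against the product of both counts divided by the genes tested.

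Genes were named by a rule fixed before the data were examined. It took the 8 highest and 8 lowest log2 fold changes past the threshold in each genotype comparison, up to 4 members past it with the smallest p from each list whose test passed or that held at least 2 such members, and Sod1. For interactions and ages it took 5 genes in each direction, of shared genes all up to 10, and the 3 smallest p-values where no gene passed. Members of called lists of which none passed, and 1 probe without a symbol, were added after their values were seen. The comparisons, the lists, the design, the 12 split tests and most alternative settings were also fixed before the data were examined.

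In a self-test arrays were simulated from the means and spreads of the real genes, with normal noise drawn independently for each gene. In the G93A-SOD1 group of 100 days 200 genes were raised or lowered by 0.5, 1 or 2 log2 units. The procedure recovered 40.5%, 81.5% and 99% of them in spinal cord, 42%, 90% and 99% in muscle and 28%, 90% and 100% in blood, and called 0 genes at 70 days, where nothing was changed. Between 2.17% and 7.95% of its calls were false. Correlation between genes was not simulated. Camera found the 1 raised list of 30 and called 0 others.

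The alternatives were no background correction, all tissues normalized together, median centring in place of quantile normalization, no detection filter, every probe, only the groups compared, array weights, a trended robust variance, the replicate number as a block, and the series matrix values. Fits without 2 dim spinal cord arrays, without 3 with muscle transcripts, without these 5, and without 1 blood array of raised background were added after the data were seen. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9, with version 1.17.8 of the R package data.table.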

Results

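Gene expression was measured on 92 Illumina bead arrays in 3 tissues of G93A-SOD1 mice and of their wild type littermates, at 70 and at 100 days of age. The G93A-SOD1 line carries a mutant human superoxide dismutase 1 transgene and is a model of amyotrophic lateral sclerosis, in which motor neurons die and muscles lose their nerve supply. The tissues were the lumbar spinal cord, the left tibialis anterior (a leg muscle rich in fast fibres) and whole blood depleted of globin transcripts. Groups held 8 arrays, except that wild type at 100 days held 7 in each tissue and G93A-SOD1 muscle at 100 days held 7. Spinal cord arrays detected 5212 to 13428 probes (median 11746), muscle arrays 8512 to 11577 (median 9324.5) and blood arrays 6809 to 9691 (median 8309). The number of arrays limits the precision of every value.

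The targeted gene was examined first. Sod1 encodes a cytosolic enzyme that removes superoxide. Its probe is named for the mouse gene, and whether it also reads the human transgene is not given in the sources used here, so it does not check the genotype labels. In blood at 70 days Sod1 rose by 0.66 log2 units (SE 0.13, adjusted p = 0.0167), from 9.95 ± 0.34 (SD, n = 8) in wild type to 10.62 ± 0.17 (SD, n = 8) in G93A-SOD1; single arrays spanned 9.54 to 10.61 and 10.38 to 10.83. At 100 days the difference in blood was 0.45 (SE 0.13, adjusted p = 0.687), which passed under 1 of 11 settings, array weights (adjusted p from 0.0497 to 0.999). In muscle it was 0.16 (SE 0.09, adjusted p = 0.421) at 70 days, and at 100 days Sod1 rose by 0.33 (SE 0.10, adjusted p = 0.0326), from 11.34 ± 0.16 (SD, n = 7) to 11.67 ± 0.25 (SD, n = 7). In spinal cord Sod1 differed by less than the spread between arrays, by -0.01 (SE 0.10, adjusted p = 0.981) at 70 days and 0.11 (SE 0.10, adjusted p = 1.0) at 100 days. Of 11 alternative settings, 9 kept the call in blood at 70 days (adjusted p from 0.00651 to 0.143), and of 10 settings 8 kept that in muscle at 100 days (0.0211 to 0.248); a fit on only the groups compared and median centring ended both.

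Taldo1, which encodes transaldolase of the pentose phosphate pathway, fell in G93A-SOD1 mice in spinal cord and blood at both ages and in muscle at 100 days. In blood it fell 7.41-fold at 70 days, from 13.53 ± 0.33 (SD, n = 8) to 10.64 ± 0.58 (SD, n = 8) on the log2 scale (adjusted p = 6.24e-11). At 100 days it fell 5.88-fold, from 13.60 ± 0.27 (SD, n = 7) to 11.04 ± 0.50 (SD, n = 8; adjusted p = 4.23e-09). In spinal cord it fell 2.70-fold at 70 days and 3.00-fold at 100 days (log2 -1.43, SE 0.20, adjusted p = 0.000311; log2 -1.58, SE 0.21, adjusted p = 0.000163). In muscle it fell 1.79-fold at 100 days (log2 -0.84, SE 0.16, adjusted p = 0.00414). At 70 days Taldo1 was not called in muscle, with 9.50 ± 0.28 (SD, n = 8) against 10.26 ± 0.16 (SD, n = 8), a difference of -0.77 (SE 0.15, adjusted p = 0.0608). Median centring of the arrays ended the call in spinal cord at 100 days (-1.26, adjusted p = 0.397; range over 11 settings 1.36e-08 to 0.397) and in muscle (-0.59, adjusted p = 0.196; range over 10 settings 0.00165 to 0.196). The probe ILMN_2636384, which has no gene symbol in the platform table, moved with Taldo1. It fell by 0.62 and 0.56 log2 units in spinal cord at 70 and 100 days, by 1.02 and 0.92 in blood, and by 0.57 in muscle at 100 days (adjusted p = 0.000311, 0.00332, 1.92e-06, 4.17e-05 and 0.00414 in that order). At 70 days in muscle ILMN_2636384 was not called (-0.44, SE 0.10, adjusted p = 0.0964). Median centring ended all 5 calls of this probe (adjusted p from 0.089 to 0.757). The fit on only the groups compared ended that in spinal cord at 100 days (adjusted p = 0.107).

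**Figure D1:**
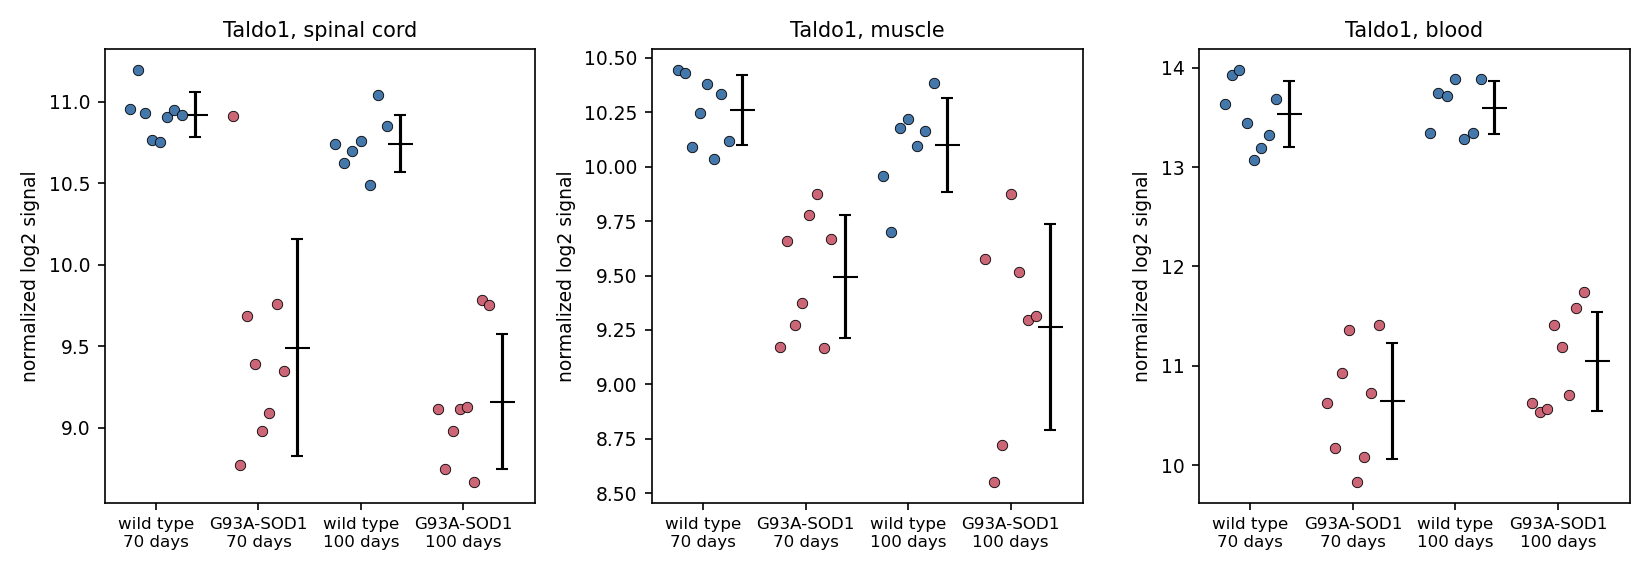
Normalized log2 signal of Taldo1 (vertical axis, with its own scale in each panel) on each array of the spinal cord, muscle and blood, by genotype and age (horizontal axis); points are arrays and black bars the mean ± SD of the group. In blood the G93A-SOD1 arrays reached at most 11.41 at 70 days against at least 13.07 in wild type, while in spinal cord 1 G93A-SOD1 array at 70 days lay at 10.91.

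In spinal cord at 70 days Taldo1, the unnamed probe above and Atp6v1d, a subunit of the proton pump that acidifies lysosomes, fell. Atp6v1d dropped by 0.91 log2 units (SE 0.15, adjusted p = 0.00243), from 11.04 ± 0.28 (SD, n = 8) to 10.12 ± 0.29 (SD, n = 8). Without 5 spinal cord arrays of doubtful quality its difference was -0.83 (adjusted p = 0.0632), and after median centring -1.39 (adjusted p = 0.475; range over 11 settings 5.94e-05 to 0.475). Limma called 3 of 10801 genes in all, each of them lower, and 541 had an unadjusted p under 0.05. If no gene differed, 540 such genes would be expected in a spinal cord comparison, 454 in muscle and 420 in blood.

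No gene list call in the spinal cord at 70 days held with an estimated correlation. Of 16 measured markers of microglia and macrophages, the immune cells of the cord, 15 had fold changes above 0 (median 0.37), and camera's test placed the list higher (adjusted p = 2.35e-06, 0.321 with an estimated correlation). Their list mean was 0.28 ± 0.47 (SD, n = 8) in G93A-SOD1, with replicate 2 at 1.34, far from the other 7 arrays at -0.04 to 0.53. Disease-associated microglia genes (median 0.18, adjusted p = 0.00115, 0.325 with an estimated correlation) and reactive astrocyte genes (median 0.26, adjusted p = 0.0137, 0.325 with an estimated correlation) were placed higher as well. So were antigen presentation (median 0.14, adjusted p = 0.00505, 0.325 with an estimated correlation), type I interferon response (median 0.22, adjusted p = 0.00496, 0.321 with an estimated correlation) and lysosome genes (median 0.10, adjusted p = 0.00496, 0.321 with an estimated correlation). Lgals3, a galectin of activated phagocytes, differed by 1.34 (SE 0.51, adjusted p = 0.74) and Aif1, a cytoskeletal protein of microglia, by 0.65 (SE 0.21, adjusted p = 0.74). Gfap, the intermediate filament of astrocytes, differed by 0.56 (SE 0.27, adjusted p = 0.74); these 3 genes were chosen after their values were seen. Of the 12 motor neuron genes 11 lay below 0 (median -0.23, adjusted p = 0.0191, 0.386 with an estimated correlation). The motor neuron list mean was -1.25 on replicate 1, the dimmest array, and -0.72 on replicate 2, and the other 6 G93A-SOD1 arrays lay between -0.23 and 0.16. Without the 2 dim arrays the motor neuron list had a median of -0.18 (adjusted p = 0.0176). No member of these lists passed the gene test over all genes (0 of each list by limma, among the 541 genes at an unadjusted p under 0.05), and 1 antigen presentation gene passed adjusted over the list alone. Without the 2 dim arrays the reactive astrocyte list had a median of 0.15 (adjusted p = 0.117). Median centring lowered the median of all genes by 0.32 log2 units and gave the lysosome list a median of -0.39 (adjusted p = 0.956) and the motor neuron list one of -0.65 (adjusted p = 0.0902); with the series matrix values antigen presentation had -0.04 (adjusted p = 0.123). Median centring also turned the medians of disease-associated microglia (-0.30), reactive astrocyte (-0.19), antigen presentation (-0.10) and interferon genes (-0.0366), whose calls against the other genes stood.

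Muscle transcripts set part of the spinal cord comparison at 70 days. Fast fibre genes had a median of -1.72 (adjusted p = 3.1e-07, 0.321 with an estimated correlation; 0 of 10 past the threshold over all genes and 6 adjusted over the list alone). Slow and oxidative fibre genes had -0.53 (adjusted p = 0.00496, 0.325 with an estimated correlation), glycolysis genes -0.45 (adjusted p = 1.25e-06, 0.321 with an estimated correlation) and oxidative phosphorylation genes -0.07 (adjusted p = 0.000207, 0.321 with an estimated correlation). The 3 arrays named here carried high levels of fibre transcripts, with fast fibre means of 4.54 and 4.52 log2 units in wild type at 70 days, replicates 3 and 5, and 2.66 in G93A-SOD1 at 100 days, replicate 8; the highest of the other 28 arrays was 0.20. On these arrays Ckm, muscle creatine kinase, reached 12.81, 12.55 and 10.08, and Acta1, skeletal actin, 14.25, 14.46 and 13.37. Without them the fast fibre list kept its call (median -0.46, adjusted p = 0.0154), and so it did without these and the 2 dim arrays (-0.37, adjusted p = 0.00345). The glycolysis list lost its call without the 3 and kept it without the 5 (-0.11, adjusted p = 0.0275). Without the 3 arrays the medians were -0.18 for slow and oxidative fibre (adjusted p = 0.613), -0.12 for glycolysis (adjusted p = 0.21) and -0.05 for oxidative phosphorylation (adjusted p = 0.378).

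At 100 days the glial lists of the spinal cord stood higher in G93A-SOD1. All 16 microglia and macrophage genes had fold changes above 0, with a median of 0.66; 10 of them rose when adjusted over the list alone and 0 over all genes tested by limma (346 genes had an unadjusted p under 0.05). The list mean was 0.73 ± 0.51 (SD, n = 8) in G93A-SOD1 and 0.07 ± 0.12 (SD, n = 7) in wild type. Irf8, a transcription factor of the microglial lineage, differed by 0.68 (SE 0.15, adjusted p = 0.164), and Fcgr3, an Fc receptor, by 0.78 (SE 0.19, adjusted p = 0.224). Gpnmb, a glycoprotein of lipid-laden phagocytes, differed by 2.43 (SE 0.65, adjusted p = 0.305) and Lgals3 by 2.15 (SE 0.53, adjusted p = 0.224). Among reactive astrocyte genes, Osmr, a receptor for the cytokine oncostatin M, differed by 1.11 (SE 0.22, adjusted p = 0.0571) and Serpina3n, a serine protease inhibitor, by 0.84 (SE 0.26, adjusted p = 0.566). These 6 genes were chosen after their values were seen. With the replicate number as a block 8 genes were called at this age, 6 of them higher, and 3 of the genes above passed. Fcgr3 then had an adjusted p of 0.0326 (range over 11 settings 0.0326 to 0.753), and Lgals3 and Osmr had 0.0438 each (0.0438 to 0.716).

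Camera's test passed for the microglia and macrophage list (adjusted p = 3.56e-22, 0.014 with an estimated correlation). It also passed for disease-associated microglia (median 0.27, 15 of 17 above 0, adjusted p = 1.8e-09, 0.0439 with an estimated correlation) and for reactive astrocytes (median 0.49, 10 of 11 above 0, adjusted p = 3.72e-09, 0.014 with an estimated correlation). Adjusted over the list alone, 2 disease-associated microglia genes and 4 reactive astrocyte genes rose. Lysosome genes (median 0.14, adjusted p = 2.81e-05, 0.0439 with an estimated correlation; 2 adjusted over the list alone), heat shock genes (median 0.22, adjusted p = 0.00208, 0.014 with an estimated correlation) and monocyte genes (median 0.42, adjusted p = 0.0111, 0.0439 with an estimated correlation) were higher too. The estimated correlation ended 3 calls, those of motor neuron genes (median -0.12, adjusted p = 0.0157, 0.329 with it), cholesterol synthesis genes (median -0.14, adjusted p = 0.00137, 0.26 with it) and proliferation genes (median 0.22, adjusted p = 0.0181, 0.146 with it). Median centring raised the median of all genes by 0.24 and ended the calls of heat shock (adjusted p = 0.108) and cholesterol synthesis genes (median 0.17, adjusted p = 0.124), and the series matrix values ended that of proliferation genes (adjusted p = 0.0774). The median of motor neuron genes turned under median centring (0.0670, adjusted p = 0.0229). Taldo1 and ILMN_2636384 were the 2 calls among single genes at 100 days, both lower.

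**Figure D2:**
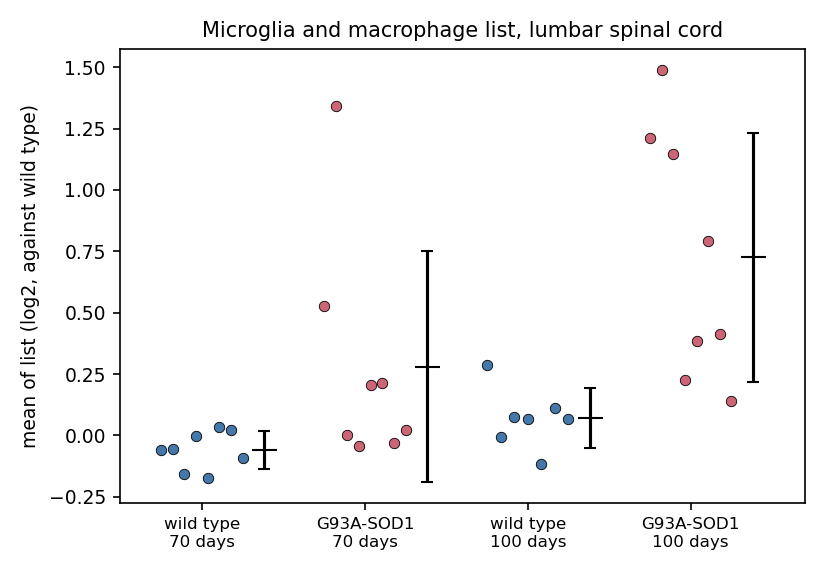
Mean of the 16 microglia and macrophage genes on each spinal cord array, as the log2 difference from the mean of all wild type arrays (vertical axis), by genotype and age (horizontal axis); points are arrays and black bars the mean ± SD of the group. G93A-SOD1 arrays spanned -0.04 to 1.34 at 70 days and 0.14 to 1.49 at 100 days, and wild type arrays -0.17 to 0.29.

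Whether the genotype effect in spinal cord changed between the ages was tested as an interaction. No gene passed (0 of 10801 by limma, 433 with an unadjusted p under 0.05). The 3 smallest p-values belonged to Sstr4, a somatostatin receptor, with a change of 0.56 (SE 0.15), Desi2 with 1.05 (SE 0.29) and Osmr with 1.10 (SE 0.31), each at an adjusted p of 0.803. The microglia and macrophage list had a median change of 0.26 (adjusted p = 0.0567), so its larger shift at 100 days was not shown to differ from that at 70 days. In wild type mice alone, no gene differed between 100 and 70 days (0 by limma, 289 with an unadjusted p under 0.05). Gpr17, a receptor of maturing oligodendrocytes, was nearest, with 8.19 ± 0.14 (SD, n = 7) at 100 days and 8.78 ± 0.18 (SD, n = 8) at 70 days (adjusted p = 0.0713). Gpr17 passed under 2 of 11 settings (adjusted p from 0.0125 to 0.881). Cyp2e1 differed by 0.49 (SE 0.12) and Cyp26b1, which breaks down retinoic acid, by 0.80 (SE 0.20), both at an adjusted p of 0.999. Heat shock genes were lower at 100 days (median -0.21, adjusted p = 0.0014, 0.0199 with an estimated correlation; 1 of 7 adjusted over the list alone), a call lost without the 3 arrays with muscle transcripts (adjusted p = 0.1) and after median centring (adjusted p = 0.136). Fibre lists and metabolic lists moved with these arrays. Fast fibre genes had a median of -1.63 (adjusted p = 8.57e-10, 0.231 with an estimated correlation) and slow and oxidative fibre genes one of -0.59 (adjusted p = 0.00483, 0.365 with an estimated correlation). Glycolysis genes had -0.33 (adjusted p = 3.79e-08, 0.202 with an estimated correlation) and oxidative phosphorylation genes -0.05 (adjusted p = 0.00483, 0.507 with an estimated correlation). Without the 3 arrays fast fibre genes had a median of -0.28 and slow and oxidative fibre genes -0.07. Glycolysis genes then had -0.10 and oxidative phosphorylation genes -0.0143, and none of these lists was called (camera adjusted p = 0.177, 0.784, 0.407 and 0.94 in that order). Antigen presentation genes were placed higher (12 of 12 above 0, median 0.29, adjusted p = 1.4e-06, 0.156 with an estimated correlation) and myelin genes lower (median -0.11, adjusted p = 0.0242, 0.243 with an estimated correlation). The series matrix values turned the median of antigen presentation genes (-0.0642, adjusted p = 0.00195). In these values replicate 5 of wild type at 100 days, a dim array, had a median of 6.38, against 7.42 on the other wild type arrays. The series matrix values also ended the call of myelin genes (median -0.13, camera adjusted p = 0.507), as did median centring (-0.36, camera adjusted p = 0.15).

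Muscle at 100 days differed most widely: 995 of 9089 genes changed, 557 higher and 438 lower in G93A-SOD1. Of the 995, 877 have a gene symbol and the rest are probes without one. Genes that muscle switches on when it loses its nerve were among those that rose. Chrng, the subunit of the fetal acetylcholine receptor, rose from a level above background on 0 of 7 wild type arrays to 9.43 ± 1.65 (SD, n = 7), at least 18.5-fold (adjusted p = 0.00604). Such a bound, given wherever no array of a group detected the probe, divides the bright group's mean by the dim group's mean after each dim array was raised to its lowest detected signal where its own was lower. Of 14 measured denervation response genes 12 rose, both over all genes and adjusted over the list alone, with a median of 1.68 (camera adjusted p = 1.6e-10, 0.202 with an estimated correlation). They included Gadd45a, a stress-response gene induced by denervation (2.76, SE 0.49), Runx1, a transcription factor (at least 5.62-fold), and Ncam1, a cell adhesion molecule of immature and denervated fibres (2.43, SE 0.50). The list mean was 1.87 ± 0.87 (SD, n = 7) in G93A-SOD1 and -0.03 ± 0.08 (SD, n = 7) in wild type.

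**Figure D3:**
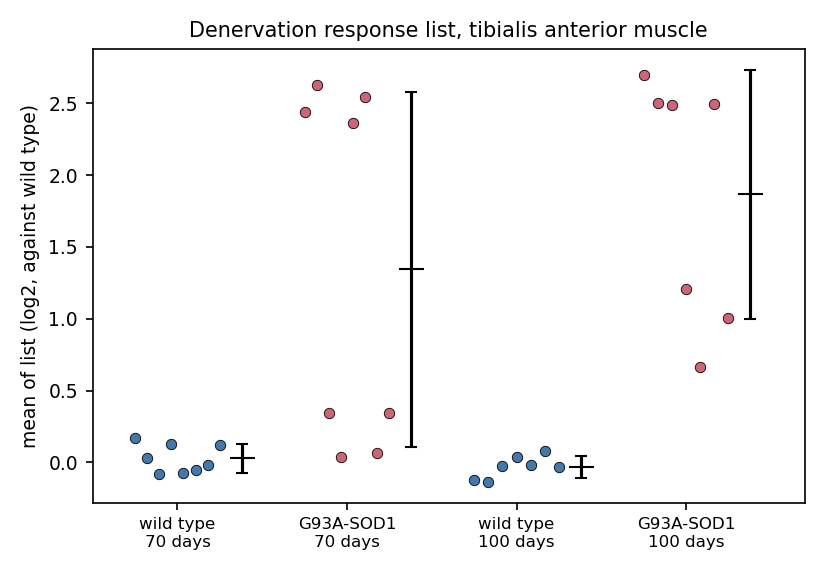
Mean of the 14 denervation response genes on each muscle array, as the log2 difference from the mean of all wild type arrays (vertical axis), by genotype and age (horizontal axis); points are arrays and black bars the mean ± SD of the group. G93A-SOD1 arrays spanned 0.04 to 2.63 at 70 days and 0.67 to 2.70 at 100 days, against -0.14 to 0.17 in wild type.

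The other genes with the highest fold changes in muscle at 100 days were Krt8 and Krt18, keratins that pair into intermediate filaments (at least 13.9-fold and 18.3-fold), and Aldh3a1, an aldehyde dehydrogenase (at least 7.47-fold). Rrad, a small GTPase that restrains calcium channels, rose by 4.33 (SE 0.68, adjusted p = 0.00148), Aif1l, an actin-binding protein, by 3.67 (SE 0.82) and Ankrd1, a stretch-responsive ankyrin repeat protein, by 3.31 (SE 0.69). The largest decreases were those of Lrrc38, a potassium channel subunit (-1.85, SE 0.43), Tspan8, a tetraspanin (-1.78, SE 0.49), and Myh4, the fastest myosin heavy chain (-1.73, SE 0.52). Mbp, myelin basic protein, followed with -1.68 (SE 0.38), Mybpc2, fast myosin-binding protein C, with -1.66 (SE 0.52) and Tigar, which lowers glycolytic flux, with -1.60 (SE 0.35). Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, had -1.57 (SE 0.47) and Gpt2, mitochondrial alanine aminotransferase, -1.56 (SE 0.41). Adjusted p-values of these genes lay between 0.00148 and 0.038.

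Those fibre type genes that passed in muscle at 100 days went up for slow and down for fast fibres. Of 11 slow and oxidative fibre genes 4 rose, the same number adjusted over the list alone (median 0.68, camera adjusted p = 0.00309, 0.292 with an estimated correlation): the slow troponins Tnni1 (3.02, SE 0.81), Tnnt1 (2.53, SE 0.70) and Tnnc1 (2.35, SE 0.78), and Atp2a2, the slow calcium pump (1.95, SE 0.55). Of 12 fast fibre genes 3 fell, also 3 adjusted over the list alone (median -0.07, mean -0.39, camera adjusted p = 0.0205, 0.292 with an estimated correlation): Myh4, Mybpc2 and Casq1, the calcium store protein calsequestrin (-0.66, SE 0.20). Glycolysis genes went the same way, with 5 of 12 lower over all genes and over the list alone (median -0.30, camera adjusted p = 0.00335, 0.292 with an estimated correlation). Pygm, muscle glycogen phosphorylase, fell by 0.99 (SE 0.28), Gpd1, a glycerol phosphate dehydrogenase, by 1.20 (SE 0.36), Phkg1, a phosphorylase kinase subunit, by 1.00 (SE 0.31) and Pfkm, muscle phosphofructokinase, by 0.33 (SE 0.10). Oxidative phosphorylation genes had a median of -0.15 with 0 of 35 past the threshold by limma over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00297, 0.292 with an estimated correlation).

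Some members of the stress, myogenesis and wasting lists rose in muscle at 100 days, while no list call held with an estimated correlation. Among NRF2 and antioxidant genes 5 of 13 rose and 1 fell, the same numbers adjusted over the list alone (median 0.35, camera adjusted p = 0.0049, 0.202 with an estimated correlation). The metallothioneins Mt1 (1.28, SE 0.27) and Mt2 (0.92, SE 0.17) rose, as did Hmox1, heme oxygenase (1.27, SE 0.24), and Srxn1, sulfiredoxin (0.81, SE 0.17). Of 10 muscle atrophy genes 5 rose, also 5 adjusted over the list alone (median 0.38, camera adjusted p = 0.0072, 0.202 with an estimated correlation), among them the autophagy genes Map1lc3a (0.89, SE 0.25) and Sqstm1 (0.56, SE 0.17), the proteasome subunit Psmc4 (0.34, SE 0.11) and the transcription factor Foxo1 (0.69, SE 0.22). Of 5 satellite cell and myogenesis genes 3 rose, and 4 adjusted over the list alone (median 0.88, camera adjusted p = 0.00838, 0.282 with an estimated correlation): Myf6 (1.07, SE 0.30), the fusion protein Mymk (1.08, SE 0.32) and Myog (at least 1.13-fold), which the denervation list also holds. Of 6 heat shock genes 2 rose, Hspb8 (0.90, SE 0.26) and Dnajb1 (0.45, SE 0.13), and 4 adjusted over the list alone (camera adjusted p = 0.00309, 0.282 with an estimated correlation). Of 8 immediate early genes 2 rose, Junb (1.48, SE 0.42) and Jun (0.66, SE 0.22), and 3 adjusted over the list alone (camera adjusted p = 0.0166, 0.282 with an estimated correlation). The axon injury list, which shares Gadd45a and Jun with lists above, held 3 of 6 genes that rose, with Sox11 (at least 1.21-fold), and 4 adjusted over the list alone (camera adjusted p = 0.0242, 0.282 with an estimated correlation).

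Some matrix and immune cell genes also rose in muscle at 100 days. Of 14 extracellular matrix genes 4 rose, and 6 adjusted over the list alone (median 0.58, camera adjusted p = 0.000818, 0.282 with an estimated correlation): the collagen cross-linking enzymes Lox (1.07, SE 0.33) and Loxl1 (0.72, SE 0.17), the proteoglycan Bgn (0.83, SE 0.21) and Timp1, an inhibitor of matrix proteases (1.51, SE 0.40). Of 13 microglia and macrophage genes 2 rose, Aif1 (0.54, SE 0.14) and the chemokine receptor Cx3cr1 (at least 1.05-fold), and 5 adjusted over the list alone (median 0.54, camera adjusted p = 0.000773, 0.282 with an estimated correlation). From the disease-associated microglia list 3 of 16 rose and 1 fell, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.0139, 0.282 with an estimated correlation). These were Lgals3 (2.89, SE 0.56), Gpnmb (1.28, SE 0.40), the lysosomal membrane protein Cd63 (0.45, SE 0.12) and, lower, Ank, a pyrophosphate transporter (-0.62, SE 0.19). The astrocyte reactivity list held 4 of 10 genes that rose, and 6 adjusted over the list alone (camera adjusted p = 0.00309, 0.202 with an estimated correlation). None of them is specific to astrocytes. They were Timp1, Serpina3n (1.17, SE 0.36), the membrane protein Emp1 (0.58, SE 0.18) and Cd109, a surface glycoprotein that binds growth factor receptors (0.32, SE 0.10). Of 15 lysosome genes 2 rose, the protease Lgmn (1.16, SE 0.21) and Cd63, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0608). Antigen presentation genes had 0 of 12 past the threshold by limma (H2-Eb1, a class II chain chosen after its value was seen, 0.80, SE 0.31, adjusted p = 0.0894; list adjusted p = 0.0486, 0.292 with an estimated correlation). H2-Eb1 passed under 3 of 10 settings (adjusted p from 0.0311 to 0.204). Median centring ended the calls of the antigen presentation list (camera adjusted p = 0.113) and of the axon injury list above (camera adjusted p = 0.0741). The myelin list was lower, with Mbp the 1 of 6 that fell and 2 adjusted over the list alone (median -0.56, camera adjusted p = 0.0128, 0.282 with an estimated correlation). Of 5 proliferation genes the kinase Aurka fell (-1.02, SE 0.27) and Mcm5, of the replication helicase, rose (0.55, SE 0.18). That list was not placed apart (median 0.03, mean -0.02, camera adjusted p = 0.725), and 2 members rose and 1 fell adjusted over the list alone.

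The muscle calls depended on the scaling and on the detection filter. Without the filter 502 genes changed, and 33 of the 63 called genes named for muscle kept their call. Other settings ended single calls too: Foxo1 (adjusted p from 0.0427 to 0.124) and Sox11 (0.0186 to 0.111) kept theirs under 5 of 10 settings, and Mcm5 (0.0178 to 0.0906) and Tnnc1 (0.0192 to 0.154) under 6. Every other called gene named for muscle at 100 days kept its call under at least 7. Median centring gave 43 calls in place of 995, 36 higher and 7 lower (83.7% higher against 56.0%), and raised the median of all genes by 0.19 log2 units; of the same 63 genes, 13 kept their call under it, Chrng among them (adjusted p from 8.72e-05 to 0.0277 over 10 settings).

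At 70 days 1 gene changed in muscle: Polk, a DNA polymerase that copies damaged templates, fell by 1.05 log2 units (SE 0.18, adjusted p = 0.019), from 6.30 ± 0.17 (SD, n = 8) to 5.25 ± 0.49 (SD, n = 8). Of 10 alternative settings 6 kept this call (adjusted p from 0.0175 to 0.606). Polk was not called in muscle at 100 days, where wild type lay lower than at 70 days. It then had 5.64 ± 0.48 (SD, n = 7) in wild type and 5.24 ± 0.23 (SD, n = 7) in G93A-SOD1. For 70 days limma gave 1407 of 9089 genes an unadjusted p under 0.05, where 454 would be expected if none differed. The denervation response list had a median of 1.15 and 13 of 14 genes above 0, and 12 rose adjusted over the list alone against 0 over all genes (camera adjusted p = 8.02e-11, 0.35 with an estimated correlation). Gadd45a differed by 2.18 (SE 0.46, adjusted p = 0.0649) and Runx1 by at least 2.90-fold (adjusted p = 0.132); both were chosen after their values were seen. With the replicate number as a block Gadd45a passed (adjusted p = 0.048, range over 10 settings 0.048 to 0.606). The G93A-SOD1 arrays lay apart from one another, with a list mean of 1.35 ± 1.23 (SD, n = 8) against 0.03 ± 0.10 (SD, n = 8) in wild type. Replicates 1, 2, 5 and 6 had 2.44, 2.63, 2.37 and 2.55, and replicates 3, 4, 7 and 8 had 0.34, 0.04, 0.07 and 0.34.

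Camera placed 9 further lists apart in muscle at 70 days, none of which held with an estimated correlation. Higher were axon injury (median 0.73, adjusted p = 0.0111, 0.35 with an estimated correlation; 3 adjusted over the list alone) and heat shock genes (0.37, adjusted p = 0.0111, 0.405 with it; 2). So were NRF2 and antioxidant (0.20, adjusted p = 0.0128, 0.35 with it; 3) and slow and oxidative fibre genes (0.36, adjusted p = 0.0128, 0.541 with it; 2). Muscle atrophy (0.17, adjusted p = 0.0294, 0.35 with it), extracellular matrix (0.26, adjusted p = 0.0294, 0.541 with it) and immediate early genes (0.64, adjusted p = 0.0294, 0.405 with it; 2 adjusted over the list alone) were higher too. Glycolysis (-0.22, adjusted p = 0.00371, 0.46 with an estimated correlation; 2 adjusted over the list alone) and oxidative phosphorylation genes (-0.10, adjusted p = 0.0329, 0.598 with it) were lower. Median centring ended the calls of heat shock, NRF2, atrophy and matrix genes (adjusted p = 0.0529, 0.0521, 0.119 and 0.0529).

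The change of the genotype effect from 70 to 100 days reached the threshold for no gene in muscle (0 of 9089 by limma, 232 with an unadjusted p under 0.05). Lbp, a lipopolysaccharide-binding protein, had the smallest p (1.04, SE 0.26), followed by Arpc1b, of the actin-nucleating complex (0.62, SE 0.16), and Yipf1 (0.67, SE 0.19), each at an adjusted p of 0.999. The 995 calls at 100 days and 1 at 70 days were thus not shown to be different effects. In wild type muscle no gene differed between the ages (0 by limma, 1072 with an unadjusted p under 0.05). The smallest p-values were those of Mmrn1, an endothelial and platelet protein (at least 1.21-fold higher at 100 days), Ehd1, of endocytic recycling (-0.70, SE 0.15), and Abi3 (-0.80, SE 0.17), each at an adjusted p of 0.104. All 3 passed with array weights (adjusted p = 0.0294 each, range over 10 settings 0.0294 to 0.987). The myelin list was placed higher at 100 days (median 0.56, adjusted p = 0.0135, 0.351 with an estimated correlation; 2 of 6 adjusted over the list alone).

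In blood at 70 days 6 of 8403 genes changed, 1 higher (Sod1) and 5 lower, and 528 had an unadjusted p under 0.05. Besides Taldo1 and ILMN_2636384, Stat2, a transcription factor of interferon signalling, fell at least 1.49-fold (adjusted p = 0.00153), being above background on 6 of 8 wild type arrays and on 0 of 8 G93A-SOD1 arrays. Flii, an actin-remodelling protein, fell by 1.02 (SE 0.19, adjusted p = 0.0143) and Lsm4, of RNA splicing and decay, by 0.78 (SE 0.16, adjusted p = 0.0429). Of 11 alternative settings 10 kept the calls of Stat2 (adjusted p from 0.000207 to 0.0543) and Flii (0.00557 to 0.422), and 5 that of Lsm4 (0.00861 to 0.422); without the wild type array of raised background Lsm4 had an adjusted p of 0.131.

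White cell lists moved in blood at 70 days without single genes passing over all genes. B cell genes were placed higher, 11 of 12 above 0 (median 0.40, camera adjusted p = 3.81e-05, 0.163 with an estimated correlation), and 3 rose adjusted over the list alone. Vpreb3, of the pre-B cell receptor, differed by 0.58 (SE 0.14, adjusted p = 0.203) and the B cell receptor regulator Cd72 by 0.61 (SE 0.17, adjusted p = 0.353), both chosen after their values were seen. Lysosome genes were lower (median -0.23, adjusted p = 0.00056, 0.0481 with an estimated correlation), as were the disease-associated microglia list (median -0.14, adjusted p = 0.00173, 0.0481 with it) and ER stress genes (median -0.13, adjusted p = 0.00761, 0.0481 with it). Calls that the estimated correlation ended were those of macrophage genes (median -0.21, adjusted p = 2.83e-05, 0.105 with it; 1 lower adjusted over the list alone) and monocyte genes (-0.20, adjusted p = 0.00453, 0.16 with it). It also ended those of neutrophil (-0.14, adjusted p = 0.021, 0.573 with it) and cytotoxic cell genes (-0.22, adjusted p = 0.00594, 0.247 with it). Fast fibre (-0.48, adjusted p = 0.0132, 0.418 with an estimated correlation) and glycolysis genes (-0.11, adjusted p = 0.0488, 0.139 with it) were lower too, the latter not without the array of raised background (adjusted p = 0.107). Median centring raised the median of all genes by 0.23 and turned the medians of lysosome (0.14, adjusted p = 0.11) and glycolysis genes (0.19, adjusted p = 0.483). The medians of disease-associated microglia (0.14), ER stress (0.18), neutrophil (0.16) and cytotoxic cell genes (0.0262) turned as well, while their calls against the other genes stood.

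At 100 days 5 genes changed in blood, 3 lower and 2 higher, with 196 at an unadjusted p under 0.05. Lsm4 fell by 0.89 (SE 0.17, adjusted p = 0.0151), with Taldo1 and ILMN_2636384. The 2 that rose have no symbol, ILMN_1238221 by 1.07 (SE 0.19, adjusted p = 0.00986) and ILMN_1233733 by 1.00 (SE 0.20, adjusted p = 0.0371), the latter outside the rule for named genes and chosen after its value was seen. Lsm4 kept its call under 9 of 11 settings (adjusted p from 0.00176 to 0.998), ILMN_1238221 under 10 (0.00225 to 0.546) and ILMN_1233733 under 7 (0.000811 to 0.998). Median centring ended the call of ILMN_1238221 (1.20, adjusted p = 0.546). Flii and Stat2, called at 70 days, were not called at 100 days, though both lay lower in G93A-SOD1. Flii had 6.68 ± 0.44 (SD, n = 8) against 7.60 ± 0.38 (SD, n = 7) in wild type. Stat2 had 4.58 ± 0.13 (SD, n = 8) against 5.40 ± 0.54 (SD, n = 7). Neutrophil genes were placed higher, 14 of 14 above 0 (median 0.22, camera adjusted p = 0.0192, 0.706 with an estimated correlation). Cxcr2, their chemokine receptor, differed by 0.49 (SE 0.22, adjusted p = 1.0) and was chosen after its value was seen. Monocyte genes (median -0.30, adjusted p = 0.0192, 0.439 with an estimated correlation) and the disease-associated microglia list (median -0.11, adjusted p = 0.0192, 0.259 with it) were placed lower. Under median centring the latter had a median of 0.0233 (adjusted p = 0.00257).

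No gene in blood showed a change of the genotype effect between the ages (0 of 8403 by limma, 120 with an unadjusted p under 0.05). The urea transporter Slc14a1 (-0.94, SE 0.25), the urate transporter Slc2a9 (-0.55, SE 0.15) and Mfsd6 (0.79, SE 0.26) had the smallest p-values, each with an adjusted p of 1.0. In wild type blood 0 genes differed between the ages by limma and 814 had an unadjusted p under 0.05. Nearest among named genes were Eno3, muscle enolase (0.60, SE 0.12, adjusted p = 0.12), Slc14a1 (0.86, SE 0.18, adjusted p = 0.144) and Rpl3l, a muscle form of a ribosomal protein (1.02, SE 0.22, adjusted p = 0.169). Slc14a1 passed with the replicate number as a block (adjusted p = 0.0268, range over 11 settings 0.0268 to 0.996).

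Calls shared between comparisons were few. Within a tissue, 2 genes fell at both ages in spinal cord (Taldo1 and ILMN_2636384; 0.000556 for independent lists), 3 in blood (with Lsm4; 0.00179) and 0 in muscle (0.0482 for independent lists), where limma called 1 gene at 70 days against 1407 with an unadjusted p under 0.05. Across tissues at 70 days, Taldo1 and ILMN_2636384 fell in spinal cord and blood (0.00198 for independent lists), and muscle shared 0 genes with either. At 100 days the same 2 fell in spinal cord and muscle (0.0938), in spinal cord and blood (0.000792) and in muscle and blood (0.129), and ILMN_1238221 rose in muscle, by 0.51 (SE 0.15, adjusted p = 0.0273), and in blood (0.124 for independent lists). Its call in muscle was lost under 2 of 10 settings, median centring and no detection filter (adjusted p from 0.00984 to 0.183). No shared gene went opposite ways.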

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

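Every group was screened for single arrays far from the rest with Dixon's test, in 152 groups of values, and 19 held such an array. Chance alone marks about 1 in 20 groups. Atp6v1d, the proton pump subunit, stood far above the rest of its group on replicate 1 of G93A-SOD1 at 100 days in blood (9.13), muscle (10.16) and spinal cord (11.14), and far below on replicate 8 of wild type spinal cord at 70 days (10.43). Replicate 8 of wild type at 70 days was also the lowest of its group in muscle (8.96) and blood (8.28), though not far by the test. Erdr1, a gene of the sex chromosomes, stood apart on replicate 1 of wild type at 100 days in muscle (5.47) and spinal cord (5.37). The dimmest spinal cord array, replicate 1 of G93A-SOD1 at 70 days, detected 5212 probes and gave far values for Taldo1 (10.91), Flii (4.68), Lsm4 (5.61) and Polk (4.62). Taldo1 was also far on replicate 2 of wild type spinal cord at 70 days (11.20). Sod1 was far on replicate 2 of wild type muscle at 100 days (11.02) and on replicate 2 of G93A-SOD1 spinal cord at 70 days (12.45), the array whose microglia and macrophage list mean was far above its group (1.34). In blood, B cell genes were low on replicate 7 of wild type at 100 days (-0.81), Stat2 was far on replicate 7 of G93A-SOD1 at 100 days (4.88) and ILMN_2636384 on replicate 8 of wild type at 70 days (11.70). Fast fibre genes were high on replicate 8 of G93A-SOD1 spinal cord at 100 days (2.66).

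The genotype effect differed between the ages for 18 gene lists by camera at its preset correlation, none of which held with an estimated correlation. In muscle the medians of these changes were 0.52 for denervation response, 0.37 for reactive astrocyte, 0.34 for extracellular matrix, 0.32 for microglia and macrophage and 0.28 for antigen presentation genes. They were -0.63 for oligodendrocyte and myelin, -0.15 for oligodendrocyte precursor, -0.11 for fast fibre and -0.0555 for oxidative phosphorylation genes; median centring turned the last and ended its call (0.0371, adjusted p = 0.0525). In blood they were 0.77 for fast fibre, 0.41 for neutrophil, 0.31 for heat shock, 0.16 for ER stress, 0.12 for microglia and macrophage and -0.20 for B cell genes. The microglia and macrophage list had 0.0077 without the array of raised background, which ended its call (adjusted p = 0.262), and -0.0364 under median centring, where its call stood (adjusted p = 0.0159). In spinal cord they were 1.63 for fast fibre, 0.74 for slow and oxidative fibre and 0.42 for glycolysis genes, of which none was placed apart without the 3 arrays with muscle transcripts. Without these and the 2 dim arrays fast fibre genes passed in the opposite direction (-0.35, adjusted p = 0.0195). Median centring ended the calls of the fast fibre (adjusted p = 0.0799) and slow and oxidative fibre lists (adjusted p = 0.277).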

How the results depend on the processing

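Median centring left 116 of 189 named genes and 68 of 86 gene lists the same, and the estimated correlation weakened 76 of the 86 lists. A named gene that was not called and stayed so counts as the same, and most of the 116 were of this kind. Of the calls of named genes, 63 were lost under median centring. In muscle at 100 days 50 were lost and 13 kept. Why results moved was not tested. A list was called the same where camera still placed it the same way against the other genes. Its median turned under median centring in 16 of 86 lists, of which 11 were still called, and with the series matrix values in 2, of which 1 was. Median centring left 1 changed gene in spinal cord at 70 days and 0 at 100 days, 0 and 43 in muscle, and 1 and 1 in blood. It called 7 lists in blood at 100 days, 3 between the ages in blood and 5 between the ages in muscle. Genes shared by both ages numbered 0 in spinal cord and 1 in blood. Shared between tissues were 1 gene of spinal cord and blood at 70 days and, at 100 days, 0 of spinal cord and muscle, 0 of spinal cord and blood and 0 of muscle and blood. It turned the lysosome list of spinal cord at 70 days (-0.39) with Laptm5 (-0.0679), B2m (-0.0300), Man2b1 (-0.23) and Grn (-0.26), the neurofilament genes Nefm (0.0724) and Nefh (0.14) of spinal cord at 100 days, and Ctsz (0.0543), Hexa (0.0023), Gapdh (0.17) and Cxcr2 (0.0554) of blood at 70 days. The series matrix values gave 2 changed genes in muscle at 70 days and 1 between the ages in blood. They called 7 lists for the interaction in spinal cord, 2 between the ages in muscle and 6 in blood at 100 days. Shared genes were 1 for both ages of muscle, and at 70 days 1 for spinal cord and muscle and 1 for muscle and blood. They turned the test of oxidative phosphorylation genes (median -0.0440) and Cyp2e1 (-0.0854) between the ages of spinal cord, and Sod1 (0.0015) and Nlrc5 (-0.0090) in spinal cord at 70 days. That fit kept the 2 dim spinal cord arrays, which have another distribution in the series matrix values. Without background correction 2 genes changed in muscle at 70 days and 1 between the ages in blood, and 5 lists were called in blood at 100 days. Shared genes were then 1 for both ages of muscle, and at 70 days 1 for spinal cord and muscle and 1 for muscle and blood. Without a detection filter 0 genes changed in muscle at 70 days and 502 at 100 days. Only the groups compared gave 1 gene in spinal cord and 3 in blood at 100 days. Array weights gave 6 and 4 genes in spinal cord at 70 and 100 days and 1 between its ages, 1575 in muscle at 100 days and 18 between its ages, and 14 in blood at 100 days. A trended robust variance gave 2 genes in muscle at 70 days, and normalizing all tissues together gave 1 between the ages of spinal cord. The replicate number as a block gave 8 genes in spinal cord at 100 days, 6 in muscle at 70 days and 2 between the ages in blood. With this block 5 genes were shared by both ages of muscle, at 70 days 1 by spinal cord and muscle and 1 by muscle and blood, and at 100 days 4 by spinal cord and muscle. Within a tissue, arrays of one number correlated at a mean of 0.0494 in spinal cord, 0.0668 in muscle and 0.109 in blood after group means were removed. An estimated correlation left 0 lists in spinal cord at 70 days, 0 for its interaction and 1 between its ages. In muscle it left 0 at 70 days, 0 at 100 days, 0 for the interaction and 0 between the ages, and in blood 3 at 70 days, 0 at 100 days and 0 for the interaction. The fits that left arrays out were added after the data were seen. Without 2 dim spinal cord arrays 7 lists were called for the interaction. Without the 3 arrays with muscle transcripts 1 list was called for the interaction and 2 between the ages, and fast fibre genes in the interaction (-0.0450) and the test of oxidative phosphorylation genes between the ages (-0.0143) turned. Without these 5 arrays 7 lists were called at 70 days, and 5 genes changed at 100 days and 1 between the ages. There the interaction of fast fibre genes (-0.35) turned and passed (adjusted p = 0.0195). Also turned were the test of slow and oxidative fibre genes in the interaction (0.0375), their median between the ages (0.0082) and Sod1 at 70 days (0.014). A block for the bead chip was not run, because the files used here name no chip.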

Other observations

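Atp6v1d, the subunit of the proton pump that passed in spinal cord at 70 days, lay below wild type in all 6 genotype comparisons, by -0.91 to -0.46 log2 units. Hspa2, a chaperone of the heat shock protein family, lay above wild type in all 6 (0.13 to 0.93), and Vti1b, a protein of vesicle fusion, below in all 6 (-0.37 to -0.11). These genes were picked after the values were seen, as the 3 of the 20 most evenly differing genes that lay on 1 chromosome. Others differed more evenly than Vti1b and lay below wild type in all 6 as well. Besides Taldo1 these were Lsm4 (-0.89 to -0.22), Rex1bd (-0.36 to -0.18) and Prrc2a (-0.63 to -0.25). Beyond the calls given above none of these ranges is a test.

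For Taldo1 and the unnamed probe the splits and most settings were fixed beforehand, and what every other test had to show was chosen after the result was seen. If doubtful arrays or the scaling made the decrease, it could vanish under another setting; over 76 values the Taldo1 difference nearest to 0 was -0.59 (SE 0.23), which argues against this, while that of the probe was -0.30 (SE 0.35), which leaves it open. Both were first judged together by that -0.30 without its error, and the test was restated after this form was seen. If a stretch of DNA carried along with the transgene were responsible, the 20 most evenly differing genes could cluster, and at most 3 lay on 1 chromosome against a median of 3 in 10000 random draws (permutation p = 0.93). A short stretch need not raise that count, so the explanation stays open, and Taldo1 is not on the chromosome of the 3.

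Those 3 genes were Atp6v1d, Hspa2 and Vti1b, and both tests of their neighbourhood were chosen after this was seen. They lay within a run of 7 neighbouring measured genes, where the shortest run holding 3 of 20 random genes had a median of 119 (permutation p = 0.0016). This is consistent with a stretch of DNA carried along with the transgene, though shared regulation of neighbouring genes was not tested and Hspa2 went the other way. The 40 neighbours of Atp6v1d had a mean absolute statistic of 0.582 (median of 5341 windows 0.522, 95% of windows under 0.639), which decides neither way. On replicate 1 of G93A-SOD1 at 100 days Atp6v1d lay inside or above the wild type range of that age in all 3 tissues. How this bears on such a stretch was not tested.

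The denervation list spread far wider among G93A-SOD1 muscles than in wild type, and all tests of this spread were chosen after the result was seen. If array brightness set the spread, wild type arrays with as many detected probes would reach list means over 0.5 as well. Of 10 G93A-SOD1 arrays with a mean over 1, 8 lay inside the wild type range of 8512 to 10602 detected probes. The highest wild type list mean was 0.17, which argues against brightness. If wild type muscles could sit under a G93A-SOD1 label, Taldo1 would be at the wild type level on the 4 arrays with a mean under 0.5, all of 70 days. Each lay at least 0.37 log2 units below every wild type muscle of 70 days (SD 0.16) and 0.0357 below the lowest of 100 days (SD 0.22), but ILMN_2636384 was inside the wild type range of 13.94 to 14.27 on 2 of them, replicates 7 and 8 (14.04 each), and below it on replicates 3 and 4 (13.73 and 13.67), so a wrong label stays open. The tests were restated after first forms that were left open (a highest wild type list mean of 0.17 and a Taldo1 gap of -0.17 over all G93A-SOD1 muscles), and a difference in disease onset between mice was not tested.

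For the muscle transcripts in 3 spinal cord arrays the first test was fixed before the arrays' other genes were examined, though after the raised list mean was seen, and the test of the background was restated on the deposited signal after its first form, on normalized values, was seen to be void. If muscle RNA was in these samples, other muscle genes would likely be raised too, and the smallest of the 3 median excesses over 100 such genes was 1.05, which is consistent with it. A brighter background would raise dim genes, and in the deposited signal the largest excess of the 3 arrays over the 100 dimmest genes was 0.0713 (other arrays -0.42 to 0.35), which argues against it.

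Whether arrays of different tissues with the same group and number came from 1 mouse was asked after Atp6v1d had been seen far in 3 tissues. Their deviations correlated at a mean of 0.0438 (permutation p = 0.001, the smallest the pairings drawn can give), which 1 mouse behind each number could give. The correlation was 0.0928 for spinal cord and muscle (permutation p = 0.002), 0.0216 for spinal cord and blood (permutation p = 0.126) and 0.0168 for muscle and blood (permutation p = 0.204). Within a tissue, arrays of the same number came from different mice where the genotype differed. In spinal cord, which a mouse can give only once, they also did where the age differed. Whether blood of 1 number was drawn from 1 mouse at both ages is not given in the sources used here. Arrays of the same number in different groups of a tissue correlated at means of 0.0494 in spinal cord, 0.0668 in muscle and 0.109 in blood. So a link to the number other than a shared mouse could give the correlation between tissues as well, and the test cannot tell these apart.

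The split tests, fixed before the data were examined, counted how many of 100 splits of the arrays, the real one included, called as many genes as the real labels. In spinal cord 1 split, the real one, reached the 3 genes at 70 days (highest other 2). At 100 days 2 splits reached the 2 genes (highest other 9). By the bound fixed beforehand chance was unlikely for both, though 100 splits cannot exclude it and the split with 9 called several times the real count. In muscle at 100 days 1 split reached 995 (highest other 14), and in blood at 100 days 1 reached 5 (highest other 1), where chance was unlikely as well. In muscle at 70 days 8 splits, the real one included, reached the 1 gene, and 1 of them called 1279. In blood at 70 days 6 splits, the real one included, reached the 6 genes, and 1 of them called 482. By the same bound chance stays open for these counts. Splits with several times the real count, that of spinal cord included, point to a structure of the samples or to correlation between genes, and neither was tested. For the interaction and for age the real count was 0, so all 100 splits reached it whatever the data, and these tests decide nothing. The highest other counts were 3 and 1 in spinal cord, 196 and 1 in muscle, and 1 and 2552 in blood.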
